A study of Mus musculus with 30 samples.

How the data were processed

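The data are gene counts of 30 RNA sequencing samples of mouse Achilles tendon and calcaneus. Per the labels' protocols, RNA was extracted with the PureLink RNA kit and poly-A libraries were made. Per the submitters' processing notes, reads were trimmed and checked with cutadapt 2.3, FastQC 0.11.8 and MultiQC 1.7, aligned with STAR 2.7.8a to GRCm38 and quantified with RSEM 1.3.3; the order of these steps, the annotation release and the strand setting are not given in the sources used here. The authors deposited RSEM expected counts per gene, which share reads of near-identical genes among them by an estimate. The deposited values were already whole, with 0 values that are not whole numbers among 55426 genes, so that rounding changed none. All sample columns were used. Of the gene identifiers, 55240 (99.7%) were matched by ID to GENCODE M21, which gave symbols and GRCm38 coordinates, 1-based.

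Samples were grouped by tissue, day and stimulation from their labels. Some titles call stimulated samples stimulated controls, and the group was taken as stimulated. Nothing in the labels says that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. The labels give replicate numbers 1 to 3 in every group but do not say that a number marks the same animal. Bone samples 1 and 2 of the unstimulated group at 5 days were summed into 1 library, chosen after seeing the data, because they were far closer to each other than any other pair. Markers of sex matched between all samples: Xist was at most 0.158 CPM in tendon and 0.233 CPM in bone, and Ddx3y at least 59.5 and 22.4 CPM. A covariate for sex was therefore not fitted.

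The tests, gene lists, rules for named genes and main alternatives were set before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a robust quasi-likelihood fit over all libraries of a tissue, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences between tissues were fitted over all libraries together. Each ± beside a log2 fold change is its standard error, the fold change divided by the square root of the quasi-likelihood F. All adjusted p-values of genes are edgeR's. Levels are CPM, the gene's count over the TMM-scaled library total, given as mean ± SD over libraries; log2 CPM for scores used a prior count of 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 17 comparisons were stimulated against unstimulated at each day (4), each group against naive (8), the change of the stimulation effect between days and between tissues (4), and naive tendon against naive bone (1).

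Of genes past the threshold, the text names the 12 with the largest change in each direction for stimulated against unstimulated, and 5 for comparisons with naive, among those whose libraries did not overlap between groups (10% by chance for 3 against 3), with a mean of at least 1 CPM, leaving out sex-linked and predicted genes. Where no gene passed, the 5 with the smallest p in each direction are given. Scx, Mkx, Tnmd, Col1a1, Col3a1, Tnc and Acta1 in tendon, and Sost, Dmp1, Bglap, Sp7, Acp5, Ctsk, Col1a1 and Acta1 in bone, are given for every comparison of stimulated with unstimulated. Of each list, up to 4 members with the smallest adjusted p could be named. Some genes that these rules allow are not reported here.

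Of 38 gene lists, written from textbook markers before the data were examined, 37 were tested as sets where at least 5 members were measured, and sex-linked genes served only to check samples. Lists of cell types covered tendon fibroblasts, osteoblasts, osteocytes, osteoclasts, cartilage, muscle fibres and progenitors, neutrophils, lymphocytes, macrophages, erythroid cells, megakaryocytes, adipocytes, endothelium, pericytes, Schwann cells and keratinocytes. The others covered matrix, signalling, stress, metabolism, cell cycle, clock and channel genes. In tendon 35 lists were tested, without lymphocyte and megakaryocyte genes, and in bone 37. The test was camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. With the correlation estimated from the data 0 lists passed in any of the 12 comparisons within tissues, so each list's adjusted p with an estimated correlation stands beside its call. fry of limma, which asks whether a list's genes move one way on balance, is given in the closing part.

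Alternatives were DESeq2 1.42.0 (rounded counts, Wald test), DESeq2's size factors within edgeR, no count filter, the replicate number as a block, only the libraries compared, limma-voom with quality weights, muscle and marrow scores as covariates, and leaving out each library. Added after seeing the data were the tendon score as a covariate, the scores as covariates in comparisons with naive, the near-identical pair kept as separate samples, and bone without naive replicate 3. A count of genes was called the same within 1.5 times. Each test was also tried on counts simulated with these samples' means and library sizes. Of 67 genes changed 2-fold, edgeR found 89.6% in 5-day tendon, 92.5% in 12-day tendon, 65.7% in 5-day bone and 85.1% in 12-day bone. Genes (16869, 16833, 18596 and 18649) were simulated independently, so real shares may be lower. A wider spread between libraries or fewer counts called for a larger change: the median standard error was 0.17 in 5-day tendon.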

Results

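RNA was sequenced from the Achilles tendon and from the calcaneus, the heel bone into which that tendon inserts, of mice with the genotype label Acta1,Ai32. Ai32 is a reporter allele for channelrhodopsin, a light-gated ion channel, and Acta1 encodes skeletal muscle actin. The study asked how muscle loading driven by light affects gene expression in both tissues. The 30 samples fell into 10 groups of 3: in each tissue, naive samples at day 0, and unstimulated and stimulated samples at day 5 and at day 12. Total gene counts ran from 24.5 to 44.6 M per tendon library (median 30.3 M) and from 19.3 to 35.0 M per bone library (median 23.4 M). Samples 1 and 2 of the 5-day unstimulated bone group were nearly identical beside other pairs. Their biological coefficient of variation was 2.64%, against 8.95% to 33.0% in the 29 other pairs of samples within groups. Of 12913 genes with summed counts of 20 to 2000, 8.53% differed between them beyond sampling noise, where chance gives 5% and the other pairs gave 22.2% to 49.7%. Over 15886 genes with sums of at least 50, the share was 12.4% and the chi-square per gene 6.28, against 18.8 to 208 in the other pairs and 1 for sampling noise alone. The pair thus differed by more than sampling noise, though far less than the others, and whether it is 1 library is not settled. It was counted as 1 sample, which left 14 bone libraries and 2 in that group.

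Tendon and bone libraries differed in composition. Muscle fibre genes, such as those for myosins and troponins, took 18.8% ± 2.25 of the counts of naive tendon (mean ± SD, n = 3) and 1.3% ± 1.24 of those of naive bone. Erythroid genes, led by the globins, took 0.0386% ± 0.00684 in naive tendon and 2.97% ± 1.88 in naive bone (1.89% without naive replicate 3). Neutrophil and granulocyte precursor genes took 0.000391% ± 1.93e-05 and 0.727% ± 0.333. Osteoblast genes, which include the type I collagen genes, took 3.22% ± 1.37 of the counts of naive tendon and 11.2% ± 0.414 of those of naive bone. Tendon fibroblast genes, a list that also holds the type I collagen genes, took 3.98% ± 1.55 and 11% ± 0.349. In tendon that share was 1.38% ± 0.99 and 1.32% ± 0.747 at 5 days and 0.838% ± 0.438 and 0.925% ± 0.487 at 12 days, in unstimulated and stimulated libraries. The first of these means was 0.806% without unstimulated library 3. Without naive replicate 1 the muscle fibre share of naive bone was 0.705%. Between naive tendon and naive bone, 6614 genes were higher in tendon and 6955 higher in bone, of 19845 tested with edgeR. Replicate 3 of naive bone stood apart from the other bone libraries on the first principal component, at -103, a component that held 35.8% of the variance.

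**Figure D1:**
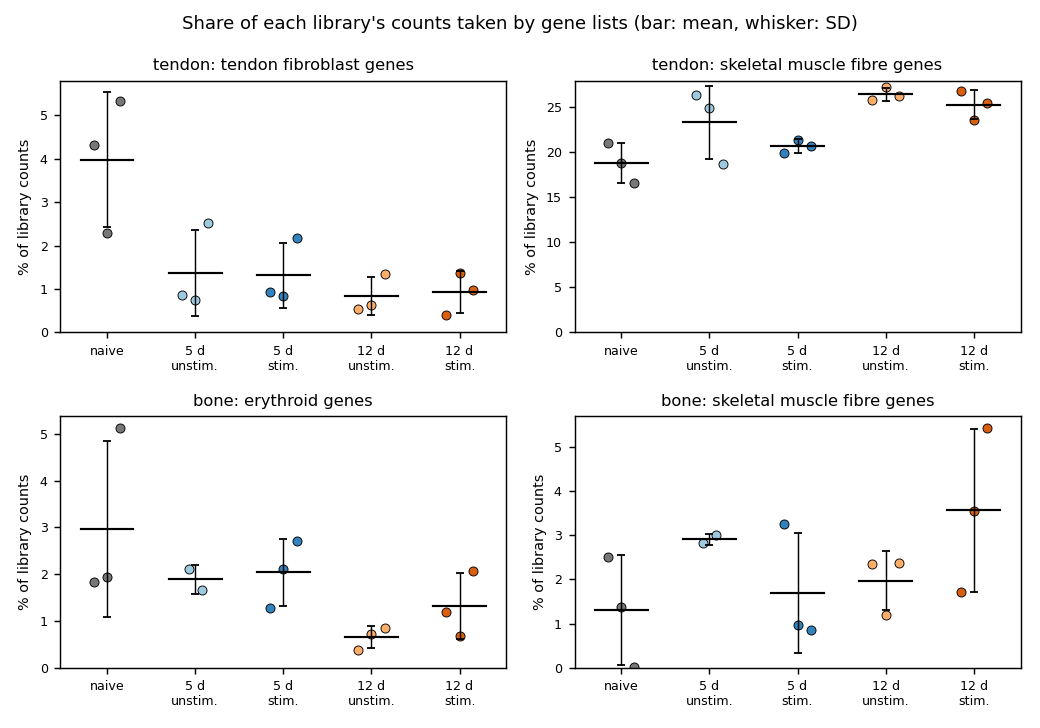
Percent of each library's counts taken by selected gene lists, 1 point per library, grouped by tissue and condition, with the group mean and SD. Muscle fibre genes took 16.5% to 27.1% of the counts of each tendon library and 0.0253% to 5.42% of each bone library.

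In tendon after 5 days, 6 genes were higher and 4 lower in stimulated than in unstimulated libraries. The higher genes were led by Sbno2, a transcriptional coregulator, at 78.7 ± 25.2 CPM against 27.1 ± 2.71 CPM (means ± SD in CPM, n = 3 and 3; log2 fold change 1.54 ± 0.21, adjusted p = 0.0231). They also held Irgm2, an interferon-inducible GTPase (1.04 ± 0.16, adjusted p = 0.0384), Eno2, which encodes a glycolytic enolase (0.94 ± 0.14, adjusted p = 0.0384), and the transcription factor gene Stat5a (0.91 ± 0.12, adjusted p = 0.0231). Smad3, a transducer of TGF-beta signals, stood at 126 ± 22.8 CPM against 70.8 ± 4.35 CPM (0.83 ± 0.12, adjusted p = 0.0283), and Hdac4, a histone deacetylase gene, rose by less (0.63 ± 0.09, adjusted p = 0.0231). The lower genes were Otud1, a deubiquitinase gene (-1.77 ± 0.27, adjusted p = 0.0412), Nr4a1, an immediate early nuclear receptor gene (-1.46 ± 0.23, adjusted p = 0.0456), Tppp3 and Tiam1, an activator of the GTPase Rac (-1.05 ± 0.14, adjusted p = 0.0231). Tppp3, a marker of tendon sheath cells, stood at 32.8 ± 3.65 CPM against 89.5 ± 18.3 CPM (-1.45 ± 0.16, adjusted p = 0.00767). In each of these genes the stimulated libraries lay wholly on the called side of the unstimulated ones. Sbno2 (ENSMUSG00000035673, chromosome 10, 80056992 to 80105571) and Tppp3 (ENSMUSG00000014846, chromosome 8, 105467493 to 105471526) are protein-coding genes, with coordinates on GRCm38.

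Among the lists in 5-day tendon, those of bone and cartilage cells stood lower than other genes after stimulation. The 19 osteoblast genes had a median log2 fold change of -1.01 (camera adjusted p = 3.46e-07, and adjusted p = 0.578 with estimated correlation). Their 5 members below the threshold when adjusted over the list alone included Smpd3 (-2.43 ± 0.50, adjusted p = 0.131), whose unstimulated mean fell from 5.27 to 3.49 CPM without unstimulated library 3, and 0 passed over all genes tested. Cartilage genes had a median of -0.72 (adjusted p = 1.32e-05, and adjusted p = 0.675 with estimated correlation) and osteoclast genes -0.48 (adjusted p = 2.9e-06, and adjusted p = 0.301 with estimated correlation). Osteocyte genes stood at -0.58 (adjusted p = 0.0196, and adjusted p = 0.412 with estimated correlation). Of the 26 immediate early genes, Nr4a1 fell and the median was -0.39 (adjusted p = 1.32e-05, and adjusted p = 0.412 with estimated correlation). Egr2 stood at -1.89 ± 0.32, adjusted p = 0.0655; adjusted over the list alone, 3 rose and 10 fell. Schwann cell genes had the lowest median, -2.28 (adjusted p = 0.000123, and adjusted p = 0.773 with estimated correlation), which rested on unstimulated library 3: their scores were 1.42, 1.74 and 4.77 log2 CPM in unstimulated and 0.979 to 1.22 in stimulated libraries. Medians were also below 0 for proteoglycans and matrix glycoproteins (-0.42; adjusted p = 4.1e-05, and adjusted p = 0.773 with estimated correlation) and cell cycle genes (-0.42; adjusted p = 3.56e-06, and adjusted p = 0.675 with estimated correlation). Collagens stood at -0.25 (adjusted p = 0.000757, and adjusted p = 0.773 with estimated correlation). YAP/TEAD and SRF targets stood at -0.37 (adjusted p = 0.000648, and adjusted p = 0.58 with estimated correlation). Muscle progenitor and regeneration genes stood higher, at 0.61 (adjusted p = 0.000485, and adjusted p = 0.675 with estimated correlation), with the neonatal myosin gene Myh8 at 2.48 ± 0.82, adjusted p = 0.421. Tendon fibroblast genes had a median of 0.14 and were not called (adjusted p = 0.939), and apart from Tppp3 no member passed. The tendon transcription factor Scx stood at 0.28 ± 0.25, adjusted p = 0.876, Mkx at 0.37 ± 0.48, adjusted p = 0.93, and tenomodulin, Tnmd, at 0.14 ± 0.60, adjusted p = 0.986. The matrix gene Col1a1 stood at -0.15 ± 0.58, adjusted p = 0.985, Col3a1 at -0.39 ± 0.33, adjusted p = 0.86, and Tnc at -0.53 ± 0.41, adjusted p = 0.835. Unstimulated library 3 stood apart on the first principal component of tendon, at -48.4, where naive libraries lay at -56.1 to -35.0 and the others of its group at -3.05 or higher. Its cartilage score was 4.27 log2 CPM against 2.76 and 2.20. Without it 7 of the 14 list calls ended: Schwann cell genes stood at -0.30 (adjusted p = 0.461), cartilage genes at -0.23 (adjusted p = 0.0540), osteocyte genes at -0.72 (adjusted p = 0.0969), proteoglycans at -0.13 (adjusted p = 0.304), YAP/TEAD and SRF targets at -0.13 (adjusted p = 0.221) and collagens at 0.0133 (adjusted p = 0.898). The other call lost was that of ribosomal protein genes. Without library 3 Col1a1 stood at 0.47 (adjusted p = 0.843) and Tnmd at 0.94 (adjusted p = 0.644). The muscle fibre share of counts was 20.6% ± 0.758 in stimulated and 23.3% ± 4.03 in unstimulated libraries, and Acta1 stood at -0.26 ± 0.16, adjusted p = 0.746.

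These 10 genes came from 17108 tested with edgeR, of which 1417 had an unadjusted p under the threshold. Leaving out a library gave 0 genes without stimulated library 1, 1 without unstimulated 1 or 2, 2 without stimulated 2, 4 without unstimulated 3 and 20 without stimulated 3. DESeq2 called 127, limma-voom with quality weights 2507, and a fit of the 6 compared libraries alone 0 (1162 at an unadjusted p).

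In tendon after 12 days, 49 genes were higher and 10 lower in stimulated libraries. The largest rise was in Atf3, a stress-induced transcription factor gene, at 53.6 to 176 CPM in the stimulated and 8.48 to 27.3 CPM in the unstimulated libraries (n = 3 and 3; log2 fold change 3.11 ± 0.53, adjusted p = 0.0301). Other genes that rose were Hbegf, an EGF receptor ligand (1.61 ± 0.25, adjusted p = 0.019), Tnfrsf12a, the receptor of the cytokine TWEAK (1.88 ± 0.35, adjusted p = 0.0482), and Nab2, a corepressor of EGR factors (1.68 ± 0.27, adjusted p = 0.0203). So did Ppargc1a, a coactivator of mitochondrial biogenesis (1.59 ± 0.30, adjusted p = 0.0482), Nmrk2, a nicotinamide riboside kinase gene of muscle (1.83 ± 0.34, adjusted p = 0.0428), and Slc25a48, a mitochondrial carrier gene (2.26 ± 0.40, adjusted p = 0.0301), as did the glycolytic genes Eno2 (1.46 ± 0.15, adjusted p = 0.00132) and Hk2, the latter at 790.0 ± 177 CPM against 296 ± 21.4 CPM (1.41 ± 0.14, adjusted p = 0.00132). The other named genes that rose were Ntsr2, a neurotensin receptor gene (2.17 ± 0.35, adjusted p = 0.0188), Ppm1e, a protein phosphatase gene (2.01 ± 0.33, adjusted p = 0.0203), Lonrf3 (1.82 ± 0.31, adjusted p = 0.0234) and Mpp3 (1.56 ± 0.29, adjusted p = 0.0396). Without unstimulated library 2 the unstimulated means of Atf3 and Slc25a48 fell from 15.1 to 9.01 CPM and from 0.481 to 0.318 CPM, and without stimulated library 3 the stimulated mean of Nmrk2 fell from 47.8 to 31.7 CPM. Among lower genes, Irx5, a homeobox transcription factor gene, had 7 counts in the stimulated libraries against 157 in the unstimulated ones, a ratio of 22.8 with a 95% counting interval of 10.8 to 57.6 (adjusted p = 0.0162). Rian, at 68.5 ± 4.74 CPM against 163 ± 37.2 CPM (-1.25 ± 0.18, adjusted p = 0.0146), and Mirg (-1.49 ± 0.21, adjusted p = 0.0138), noncoding RNA genes of the imprinted Dlk1-Dio3 region, fell. So did Tppp3 (-1.14 ± 0.16, adjusted p = 0.0138), Tiam1 (-0.91 ± 0.15, adjusted p = 0.0188), Pdcd4, an inhibitor of translation (-0.58 ± 0.08, adjusted p = 0.0143), and Ttc23 (-0.51 ± 0.09, adjusted p = 0.0375).

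Atf3 is ENSMUSG00000026628, chromosome 1, 191170296 to 191218039 on GRCm38, and Hbegf is ENSMUSG00000024486, chromosome 18, 36504927 to 36515805. Rian is ENSMUSG00000097451, chromosome 12, 109603940 to 109661716 and Mirg is ENSMUSG00000097391, chromosome 12, 109729764 to 109749460; with no strand setting stated, reads of such neighbours and of antisense transcripts cannot be told apart.

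**Figure D2:**
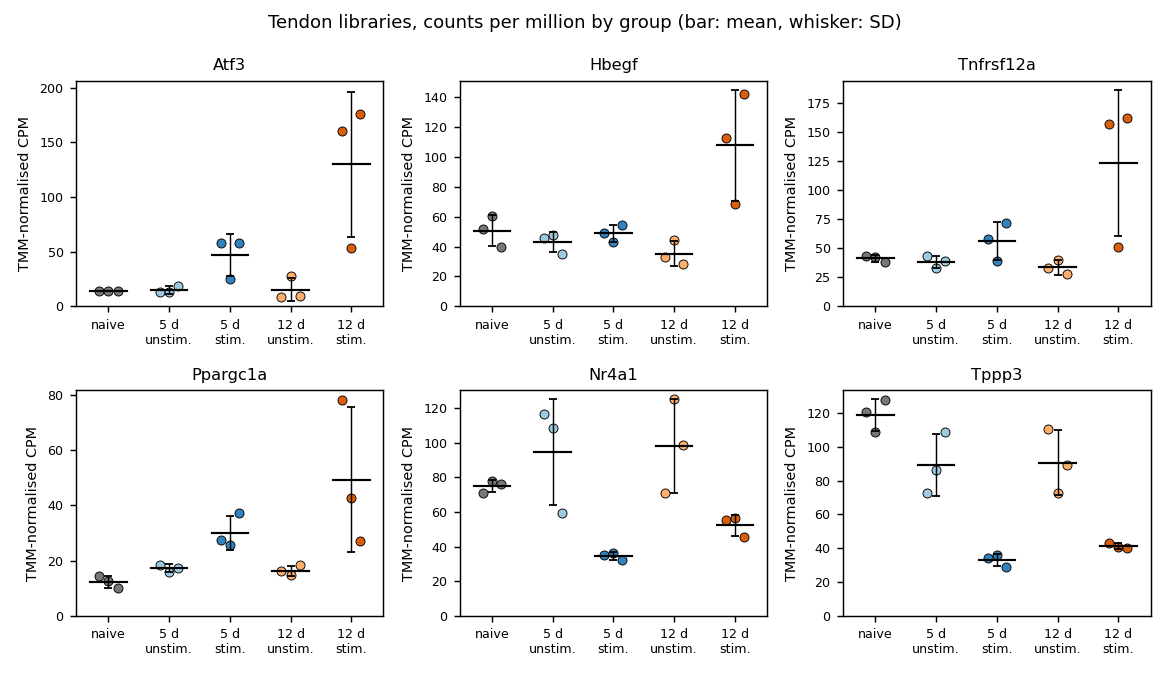
CPM of 6 named genes in each tendon library by group, on a linear axis, 1 point per library with the group mean and SD. At 12 days the stimulated libraries lay at 53.6 CPM or more for Atf3, and the unstimulated ones at 27.3 CPM or less, and Tppp3 was lower in stimulated libraries on both days.

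Among the lists in 12-day tendon, muscle progenitor and regeneration genes stood highest, with a median of 0.57 and all 13 members above 0 (adjusted p = 2.43e-05, and adjusted p = 0.684 with estimated correlation). Mymx, which encodes a fusion peptide of myoblasts, stood at 1.58 ± 0.36, adjusted p = 0.0873, Myh8 at 3.72 ± 0.86, adjusted p = 0.0938 and Chrng, an embryonic acetylcholine receptor subunit gene, at 3.18 ± 0.82, adjusted p = 0.115. Without stimulated library 3 the stimulated mean of Myh8 fell from 434 to 98.3 CPM and that of Chrng from 9.10 to 2.94 CPM. Adjusted over the list alone 5 rose, and over all genes 0. Heat shock genes had a median of 0.27 (adjusted p = 0.000727, and adjusted p = 0.684 with estimated correlation); 6 rose when adjusted over the list alone, and Hspa1a stood at 2.17 ± 0.60, adjusted p = 0.145 (stimulated mean 70.4 CPM, 39.9 CPM without stimulated library 3). Genes of the endoplasmic reticulum stress response stood lower, at -0.32 (adjusted p = 1.05e-05, and adjusted p = 0.684 with estimated correlation), with Pdia6 at -0.40 ± 0.12, adjusted p = 0.196. Interferon-stimulated genes stood at -0.27 (adjusted p = 0.000283, and adjusted p = 0.986 with estimated correlation) and endothelial genes at -0.27 (adjusted p = 0.000948, and adjusted p = 0.986 with estimated correlation). Of the immediate early genes Atf3 rose, Nr4a3 stood at 2.57 ± 0.50, adjusted p = 0.055, and the list was not called (adjusted p = 0.918, median -0.07). Of the Wnt genes Notum, a secreted Wnt deacylase gene, rose (2.79 ± 0.46, adjusted p = 0.0203), while the list was not called (adjusted p = 0.918). Hypoxia and glycolysis genes had a median of 0.17 and were not called (adjusted p = 0.0784). Tendon fibroblast genes were not called (adjusted p = 0.978, median 0.18). Scx stood at 0.34 ± 0.26, adjusted p = 0.718, Mkx at 0.39 ± 0.51, adjusted p = 0.877, and Tnmd at 0.32 ± 0.61, adjusted p = 0.924. Col1a1 stood at 0.16 ± 0.58, adjusted p = 0.966, Col3a1 at 0.07 ± 0.33, adjusted p = 0.977, and Tnc at 0.32 ± 0.42, adjusted p = 0.878. The muscle fibre share of counts was 25.2% ± 1.58 in stimulated and 26.4% ± 0.705 in unstimulated libraries, with Acta1 at 0.05 ± 0.16, adjusted p = 0.958. The interferon call ended without stimulated library 1 (-0.18, adjusted p = 0.0925), and the endothelial one without stimulated 3 (-0.06, adjusted p = 0.708) or unstimulated 1 (-0.19, adjusted p = 0.0536).

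Of 17108 genes, 1916 had an unadjusted p under the threshold. The count of 59 became 2 without unstimulated library 3, 3 without stimulated 1, 4 without unstimulated 1, 10 without stimulated 3, 18 without unstimulated 2 and 672 without stimulated 2. A fit of the 6 compared libraries alone gave 0 (1471 at an unadjusted p), the muscle score as a covariate 10, DESeq2 368 and limma-voom with quality weights 231.

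In bone after 5 days, edgeR called 0 of 18851 genes between stimulated and unstimulated libraries. Of the genes with the smallest p in each direction, those above 0 were Podnl1 (0.89 ± 0.12, adjusted p = 0.134), Arhgef19 (0.62 ± 0.09, adjusted p = 0.134), Ptprv, a phosphatase gene of osteoblasts (0.86 ± 0.13, adjusted p = 0.134), the vitamin D receptor gene Vdr (0.70 ± 0.13, adjusted p = 0.413) and Sp7. Sp7, the osteoblast transcription factor gene also called osterix, stood at 214 ± 9.97 CPM against 142 ± 26.8 CPM (n = 3 and 2; 0.59 ± 0.12, adjusted p = 0.441). Below 0 stood the desmosome gene Dsp (-4.27 ± 0.74, adjusted p = 0.293) and the skin genes Dmkn (-3.55 ± 0.59, adjusted p = 0.293) and Trim29 (-3.22 ± 0.63, adjusted p = 0.441). So did the tendon proteoglycan gene Fmod (-1.59 ± 0.29, adjusted p = 0.337) and Pde7b (-0.52 ± 0.10, adjusted p = 0.441). Osteoclast genes stood higher as a group, with a median of 0.44 (adjusted p = 4.43e-08, and adjusted p = 0.747 with estimated correlation): Acp5 stood at 0.65 ± 0.25, adjusted p = 0.552 and Ctsk at 0.65 ± 0.26, adjusted p = 0.568. Osteoblast genes stood higher as well, at 0.36 (adjusted p = 3.12e-09, and adjusted p = 0.747 with estimated correlation), with all 20 members above 0 and 3 that rose when adjusted over the list alone. Ibsp stood at 0.90 ± 0.22, adjusted p = 0.467, Bglap at 0.17 ± 0.21, adjusted p = 0.85 and Col1a1 at 0.24 ± 0.15, adjusted p = 0.717. The osteocyte genes Sost and Dmp1 stood at -0.25 ± 0.39, adjusted p = 0.885, and 0.32 ± 0.25, adjusted p = 0.761.

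Endothelial genes also stood higher in stimulated 5-day bone, at 0.30 (adjusted p = 6.76e-06, and adjusted p = 0.867 with estimated correlation). Matrix proteases and inhibitors stood at 0.27 (adjusted p = 0.000987, and adjusted p = 0.881 with estimated correlation). Genes of tissues around bone stood lower: tendon fibroblast genes at -0.74 (adjusted p = 4.43e-06, and adjusted p = 0.747 with estimated correlation) and muscle fibre genes at -0.88 (adjusted p = 0.00200, and adjusted p = 0.881 with estimated correlation). Keratinocyte genes stood at -0.93 (adjusted p = 0.000518, and adjusted p = 0.747 with estimated correlation). Acta1 stood at -0.80 ± 1.22, adjusted p = 0.882, and at -1.55 without stimulated library 1 (adjusted p = 0.736). The near-identical unstimulated pair carried skin keratin transcripts: Krt14 at 8.19 and 8.83 CPM and Krt5 at 9.03 and 11.1 CPM, against at most 0.104 and 0.414 CPM in the 13 other bone libraries. Neutrophil genes stood at -0.34 (adjusted p = 0.010, and adjusted p = 0.881 with estimated correlation) and circadian clock genes at -0.30 (adjusted p = 0.000987, and adjusted p = 0.786 with estimated correlation). Oxidative phosphorylation genes stood at -0.24 (adjusted p = 5.93e-05, and adjusted p = 0.881 with estimated correlation). Proteoglycans and matrix glycoproteins stood at -0.18 (adjusted p = 0.00399, and adjusted p = 0.881 with estimated correlation) and endoplasmic reticulum stress genes at 0.15 (adjusted p = 0.0174, and adjusted p = 0.881 with estimated correlation). Leaving out the pair or unstimulated library 3 leaves 1 unstimulated library, which is then assumed to vary like the other groups. Of the 12 list calls 6 ended without some library: keratinocyte genes stood at -0.0753 without the pair (adjusted p = 0.506) and muscle fibre genes at -0.59 without stimulated library 3 (adjusted p = 0.0741). Without unstimulated library 3, circadian clock and oxidative phosphorylation genes stood at -0.15 (adjusted p = 0.0866) and -0.16 (adjusted p = 0.0636). The neutrophil call ended without the pair or stimulated library 1 or 2, and the endoplasmic reticulum call without the pair or stimulated 3. The smallest adjusted p was 0.134, and 1522 genes had an unadjusted p under the threshold. DESeq2 called 44 genes, limma-voom with quality weights 4, and edgeR 1 without the count filter and 14 without unstimulated library 3.

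In bone after 12 days, 7 genes were lower and 0 higher in stimulated libraries. Vcan, which encodes the proteoglycan versican, stood at 49 ± 12 CPM against 134 ± 10.2 CPM (n = 3 and 3; -1.45 ± 0.20, adjusted p = 0.0419). Lgr6, an R-spondin receptor gene of Wnt signalling, stood at 11.5 ± 2.02 CPM against 28.3 ± 0.834 CPM (-1.3 ± 0.14, adjusted p = 0.0137). Also lower were Chit1, a chitinase gene of macrophages (-2.06 ± 0.30, adjusted p = 0.0419), and Stc2, which encodes the secreted glycoprotein stanniocalcin 2 (-1.08 ± 0.15, adjusted p = 0.0419). The others were Sdk2, a cell adhesion gene (-0.71 ± 0.10, adjusted p = 0.0419), Ano1, a calcium-activated chloride channel gene (-0.71 ± 0.10, adjusted p = 0.0419), and Atp2b4, a plasma membrane calcium pump gene (-0.56 ± 0.08, adjusted p = 0.0419). In each, the stimulated libraries all lay below the unstimulated ones. Vcan is ENSMUSG00000021614, chromosome 13, 89655312 to 89742509 and Lgr6 is ENSMUSG00000042793, chromosome 1, 134983301 to 135105276 on GRCm38. The bone genes always examined were not called: Sost stood at -0.32 ± 0.35, adjusted p = 0.721, Dmp1 at 0.03 ± 0.22, adjusted p = 0.96, Bglap at -0.65 ± 0.19, adjusted p = 0.202, and Sp7 at -0.17 ± 0.11, adjusted p = 0.497. Acp5 stood at -0.03 ± 0.22, adjusted p = 0.968, Ctsk at 0.14 ± 0.23, adjusted p = 0.829, Col1a1 at -0.17 ± 0.13, adjusted p = 0.602, and Acta1 at 0.75 ± 1.11, adjusted p = 0.803.

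**Figure D3:**
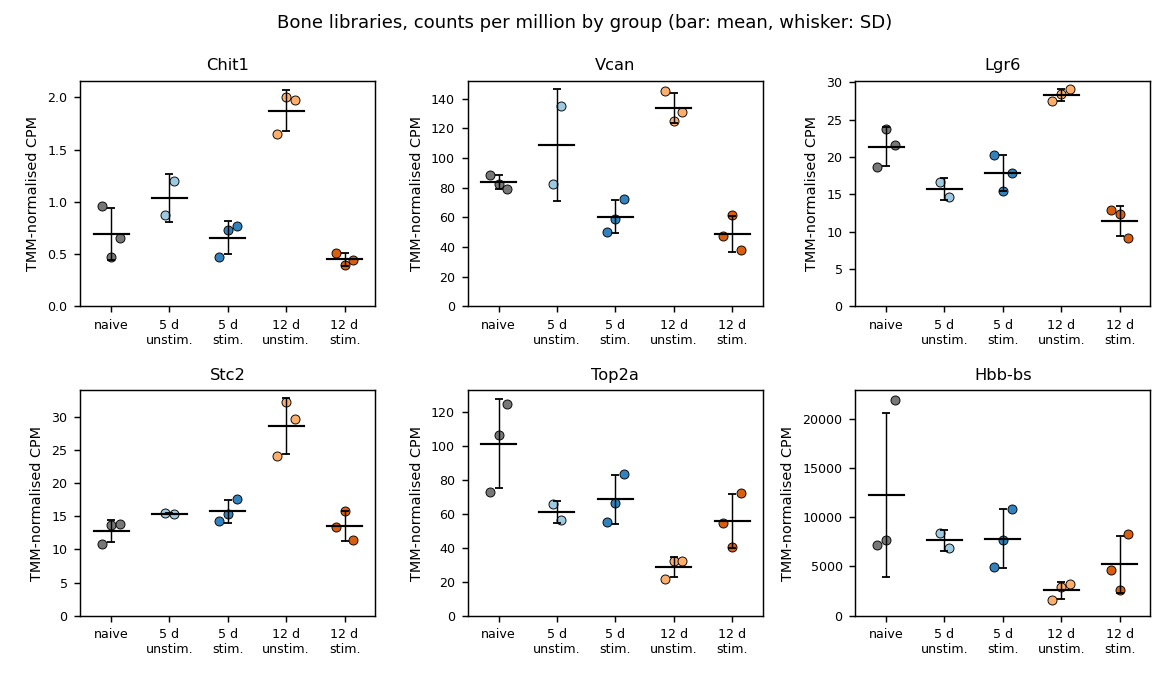
CPM of 6 genes in each bone library by group, on a linear axis, 1 point per library with the group mean and SD. Vcan and Lgr6 were lower in stimulated than in unstimulated bone at 12 days; Top2a, a cell cycle gene, and the globin gene Hbb-bs, both chosen after their values were seen, averaged 101 and 12240 CPM in naive bone (Hbb-bs 7443 CPM without naive replicate 3) and 28.8 and 2568 CPM in 12-day unstimulated bone.

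Lists of dividing and blood cells stood higher in stimulated 12-day bone. All 25 cell cycle genes were above 0, with a median of 0.84 (adjusted p = 6.03e-17). Adjusted over the list alone 24 rose, and over all genes 0; Prc1, a spindle gene, stood at 0.92 ± 0.18, adjusted p = 0.0812. Neutrophil genes had a median of 1.03 (adjusted p = 4.87e-09), with the granule gene Mpo at 1.24 ± 0.33, adjusted p = 0.185. Lymphocyte genes stood at 0.91 (adjusted p = 7.25e-09), and 11 members rose when adjusted over the list alone. The immunoglobulin gene Igkc stood at 1.41 ± 0.41, adjusted p = 0.208. Erythroid genes stood at 1.02 (adjusted p = 7.78e-07) and megakaryocyte and platelet genes at 0.79 (adjusted p = 4.53e-05). Interferon-stimulated genes stood at 0.43 (adjusted p = 4.59e-05). With estimated correlation each of these lists had adjusted p = 0.521. Except for cell cycle genes, stimulated library 2 scored within the unstimulated range (erythroid 5.45 against 4.58 to 5.95 log2 CPM). Those rises came mainly from libraries 1 and 3, and a varying marrow share stays open. The share of counts from erythroid genes was 1.32% ± 0.705 in stimulated and 0.654% ± 0.238 in unstimulated libraries, and that of muscle fibre genes was 3.56% ± 1.85 and 1.97% ± 0.67.

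Lists of stromal cells and their signals stood lower in stimulated 12-day bone. Adipocyte genes had a median of -0.52 (adjusted p = 1.01e-06), with Retn, the resistin gene, at -0.95 ± 0.27, adjusted p = 0.197. Pericyte and smooth muscle genes stood at -0.51 (adjusted p = 0.000961). Both lists had adjusted p = 0.521 with estimated correlation. Axon guidance and neurotrophin genes stood at -0.31 (adjusted p = 4.9e-06), with the semaphorin genes Sema3d at -0.65 ± 0.11, adjusted p = 0.0793 and Sema3e at -1.09 ± 0.21, adjusted p = 0.0861. Of the Wnt genes Lgr6 fell, the median was -0.27 (adjusted p = 0.00092) and 3 fell when adjusted over the list alone. TGF-beta and BMP genes stood at -0.25 (adjusted p = 2.52e-05), with the latent TGF-beta binding gene Ltbp2 at -1.15 ± 0.25, adjusted p = 0.115. These lists each had adjusted p = 0.521 with estimated correlation. Osteoblast genes stood at -0.23 (adjusted p = 8.46e-05, and adjusted p = 0.521 with estimated correlation) and collagens at -0.21 (adjusted p = 0.000135, and adjusted p = 0.602 with estimated correlation). Glucocorticoid-responsive genes stood at -0.40 (adjusted p = 0.0257, and adjusted p = 0.521 with estimated correlation). Vcan alone passed among the proteoglycans and matrix glycoproteins (-0.22; adjusted p = 0.00327, and adjusted p = 0.602 with estimated correlation).

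Of the 21 list calls 10 ended without some library. Without stimulated library 3 collagens stood at -0.0249, proteoglycans at -0.0488 (each adjusted p = 0.602) and Wnt genes at -0.12 (adjusted p = 0.132), and without stimulated 1 glucocorticoid-responsive genes stood at -0.15 (adjusted p = 0.255).

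The test in 12-day bone covered 18851 genes, of which 2757 had an unadjusted p under the threshold. The count of 7 became 0 without unstimulated library 1, 2 or 3 (1956, 2995 and 1978 at an unadjusted p), 3 without stimulated 1, 2 without stimulated 3 and 1 without naive bone replicate 3. It was 1 with DESeq2's size factors, 1 with the muscle score as a covariate, 0 with the marrow scores as covariates (916) and 0 in a fit of the 6 libraries alone (2042). The count was 32 without the count filter, 11 with the near-identical pair kept apart and 386 with DESeq2.

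The effect of stimulation was compared between days and between tissues. Between 12 and 5 days, edgeR called 0 genes in tendon (699 at an unadjusted p, smallest adjusted p = 0.668) and 0 in bone (2008, smallest adjusted p = 0.222); DESeq2 called 5 and 60. Between tendon and bone at 5 days, 0 genes were called (1248 at an unadjusted p, smallest adjusted p = 0.0832), and DESeq2 called 47. At 12 days the effect was higher in tendon for 35 genes and lower for 9. Eno2 differed by 1.74 ± 0.25 on the log2 scale (adjusted p = 0.00272), Ppm1e by 2.05 ± 0.36 (0.0114), Nab2 by 1.90 ± 0.32 (0.0114) and Hbegf by 2.28 ± 0.45 (0.0313), each with a higher effect in tendon. Tiam1 differed by -1.20 ± 0.21 (0.0117) and Pdcd4 by -0.57 ± 0.10 (0.0165). Atf3 did not pass (3.77 ± 0.80, 0.0547), nor did Stc2, which fell in bone (1.43 ± 0.32, 0.0644). DESeq2 called 190 genes for this difference. The edgeR count of 44 became 9 and 10 without tendon unstimulated or stimulated library 3, 356 without tendon stimulated 2, 23 and 25 without tendon unstimulated 1 or 2, and 23, 22, 27, 76 and 19 without bone unstimulated 1 or 3 or stimulated 1, 2 or 3.

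Unstimulated samples were compared with naive ones to show what changed over the same days without stimulation. In tendon at 5 days, genes that respond to glucocorticoids rose: Fkbp5, a chaperone of the glucocorticoid receptor, at 84.3 ± 10.3 CPM against 22.8 ± 2.18 CPM (n = 3 and 3; 1.89 ± 0.14, adjusted p = 3.86e-05), and the transcription factor gene Zbtb16 (1.02 ± 0.15, adjusted p = 0.0285). The glucocorticoid list had a median of 0.50 (adjusted p = 2.47e-06, and adjusted p = 0.114 with estimated correlation). The other genes that rose were Ppp1r3c, a glycogen-targeting phosphatase subunit gene (1.43 ± 0.22, adjusted p = 0.0481), and Mettl21e (1.41 ± 0.20, adjusted p = 0.0285). The hyaluronan receptor gene Cd44 (-0.90 ± 0.12, adjusted p = 0.0285) and the spermidine synthase gene Srm (-0.69 ± 0.10, adjusted p = 0.0285) fell. Tendon fibroblast genes stood lower, with all 19 members below 0 and a median of -1.42 (adjusted p = 1.14e-11, and adjusted p = 0.394 with estimated correlation); 14 fell when adjusted over the list alone and 0 over all genes. Inflammatory cytokines and mediators stood at -0.34 (adjusted p = 0.00122, and adjusted p = 0.264 with estimated correlation) and muscle fibre genes at 0.32 (adjusted p = 1.15e-05, and adjusted p = 0.394 with estimated correlation). The count of 6, with 1870 genes at an unadjusted p under the threshold, became 1 without naive library 1 or 2 or unstimulated 1, 2 without naive 3 or unstimulated 2, and 297 without unstimulated 3. DESeq2 called 109, and 1 or 2 were left with the muscle or tendon score as a covariate.

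In tendon at 12 days, 1397 genes were higher and 1812 lower in unstimulated than in naive libraries. Matrix genes fell: 25 of 32 collagen and crosslinking genes (median -1.2; adjusted p = 5.85e-11, and adjusted p = 0.351 with estimated correlation). Of 34 proteoglycans and matrix glycoproteins 24 fell (median -1.61; adjusted p = 7.99e-13, and adjusted p = 0.351 with estimated correlation). They included Fbn1, which encodes fibrillin 1 (-1.72 ± 0.29, adjusted p = 0.00913), the lysyl oxidase-like gene Loxl1 (-1.47 ± 0.26, adjusted p = 0.00979) and Tnc, which encodes tenascin C (-2.61 ± 0.43, adjusted p = 0.00855). Of 19 tendon fibroblast genes 11 fell, Scx among them (-1.5 ± 0.26, adjusted p = 0.00943; list median -1.76, adjusted p = 2.65e-07, and adjusted p = 0.351 with estimated correlation). Also lower were the cartilage collagen gene Col2a1 (-3.87 ± 0.79, adjusted p = 0.0131) and the protease genes Mmp9 (-5.9 ± 1.18, adjusted p = 0.0124) and Mmp13. Mmp13 had 5 counts against 551, a ratio of 70.7 with a 95% counting interval of 30.1 to 219. Bglap2, the osteocalcin paralogue, had 0 counts against 251 in naive tendon, and was thus at least 53.7-fold lower at a floor of 3 counts over the group; reads shared with Bglap make either value uncertain. Osteoblast genes had a median of -1.95 (adjusted p = 8.74e-08, and adjusted p = 0.351 with estimated correlation). Macrophage genes fell in 14 of 20 cases, Csf1r among them (-1.54 ± 0.32, adjusted p = 0.0128; adjusted p = 4.32e-07, and adjusted p = 0.351 with estimated correlation). The globin genes Hbb-bt (-2.29 ± 0.18, adjusted p = 5.82e-05) and Hba-a1 (-2.17 ± 0.18, adjusted p = 5.82e-05), near copies of other globin genes, fell with the erythroid list (median -2.02; adjusted p = 4.86e-06, and adjusted p = 0.351 with estimated correlation).

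The genes with the largest rises in 12-day unstimulated tendon were Odf3l2 (2.98 ± 0.82, adjusted p = 0.0282), Clca1 (2.98 ± 0.79, adjusted p = 0.0249), and Rasd2 (2.65 ± 0.39, adjusted p = 0.00526), followed by the calcium channel gene Cacna1i and by Irx5. Cacna1i rose by 2.64 ± 0.38 on the log2 scale (adjusted p = 0.00512) and Irx5 by 2.6 ± 0.53 (adjusted p = 0.0123). Without naive library 1 the naive means of Odf3l2 and Irx5 fell from 0.506 to 0.250 CPM and from 0.322 to 0.190 CPM. Of the muscle fibre genes 17 of 35 rose (median 0.47; adjusted p = 0.000229, and adjusted p = 0.351 with estimated correlation), and their share of counts was 26.4% ± 0.705 against 18.8% ± 2.25. Oxidative phosphorylation genes had a median of 0.27 (adjusted p = 1.37e-05, and adjusted p = 0.49 with estimated correlation) and mitochondrially encoded genes 0.27 (adjusted p = 0.00696, and adjusted p = 0.538 with estimated correlation). That of cytosolic ribosomal protein genes was 0.14 (adjusted p = 0.000229, and adjusted p = 0.517 with estimated correlation). The count of 3209 became 85 without unstimulated library 2, 207 without naive 3, 1328 without unstimulated 1, 1424 without naive 2 and 1900 without unstimulated 3. With the tendon score as a covariate 10 genes were called, and 1524 with the muscle score.

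Stimulated tendon was set against the same naive libraries. At 5 days 149 genes were higher and 243 lower. Metallothionein genes rose, Mt1 to 203 ± 29.7 CPM against 32.5 ± 7.67 CPM (2.65 ± 0.38, adjusted p = 0.0101) and Mt2 (2.34 ± 0.48, adjusted p = 0.0315). So did Card14 (2.81 ± 0.41, adjusted p = 0.0101), the synaptic vesicle gene Sv2b (3.07 ± 0.60, adjusted p = 0.027) and the acetylcholine receptor gene Chrna9 (4.18 ± 0.96, adjusted p = 0.0443). The stimulated mean of Sv2b fell from 12.5 to 6.98 CPM without stimulated library 1. Immediate early genes fell in 10 of 26 cases (list median -0.72; adjusted p = 2.81e-08, and adjusted p = 0.16 with estimated correlation). Among them were Egr2 (-2.19 ± 0.32, adjusted p = 0.00975) and Ptgs2, the inducible cyclooxygenase gene (-2.35 ± 0.35, adjusted p = 0.0101). Other genes that fell were Acan, which encodes the cartilage proteoglycan aggrecan (-2.82 ± 0.66, adjusted p = 0.0479), the retinoic acid hydroxylase gene Cyp26a1 (-3.59 ± 0.59, adjusted p = 0.0148), Mgam (-2.59 ± 0.44, adjusted p = 0.0174) and Prss35 (-2.55 ± 0.53, adjusted p = 0.0303), whose naive mean fell from 1.95 to 1.24 CPM without naive library 3. At 12 days 2026 genes were higher and 2143 lower. Myh8 (3.61 ± 0.86, adjusted p = 0.0128), the muscle gene Igfn1 (3.96 ± 0.84, adjusted p = 0.00794), Nr4a3 (3.5 ± 0.52, adjusted p = 0.00238), Rasd2 (3.43 ± 0.39, adjusted p = 0.000707) and Chrna9 (5.1 ± 0.96, adjusted p = 0.00514) rose most. Without stimulated library 3 the mean of Myh8 fell from 434 to 98.3 CPM, that of Igfn1 from 59.4 to 21.4 CPM and that of Chrna9 from 3.64 to 1.27 CPM. The hypoxia and glycolysis list stood higher (median 0.38; adjusted p = 0.00836, and adjusted p = 0.333 with estimated correlation), with Hk2 at 1.62 ± 0.14, adjusted p = 8.83e-05. Fos fell (-2.9 ± 0.37, adjusted p = 0.00105), as did Mmp9 (-6.37 ± 1.24, adjusted p = 0.00583) and Rp1 (-4.5 ± 0.83, adjusted p = 0.00477). The low stimulated means of Mmp9 (0.189 CPM) and Rp1 (0.175 CPM) were 0.0835 and 0.0626 CPM without stimulated library 3 or 2. The mechanosensitive and calcium channel genes were never called in any of the 12 comparisons of groups within a tissue: their smallest adjusted p was 0.0598, in stimulated 5-day tendon against naive, with a median of -0.17.

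The 5-day count of 392 became 7 without stimulated library 1, 23 without naive 3, 79 without stimulated 2, 177 without naive 1 and 180 without naive 2. DESeq2 called 1055, and 12 were left with the tendon score and 208 with the muscle score as a covariate. The 12-day count of 4169 became 1649 without naive library 3, 1713 without stimulated 1 and 2544 without naive 2, and 45 with the tendon score.

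In bone at 5 days, 72 genes were higher and 10 lower in unstimulated than in naive libraries. Skin genes were among the largest rises, Dmkn (3.32 ± 0.58, adjusted p = 0.0426) and Krtdap (2.3 ± 0.38, adjusted p = 0.0341), beside the keratins of the near-identical pair given above. The keratinocyte list had a median of 2.32 (adjusted p = 2.02e-05, and adjusted p = 0.434 with estimated correlation), which was 0.41 and not called without that pair (adjusted p = 0.0644). The Wnt antagonist gene Dkk2 rose to 32 ± 1.72 CPM against 9.15 ± 2.78 CPM (n = 2 and 3; 1.81 ± 0.28, adjusted p = 0.0279). So did Tmeff2 (2.21 ± 0.31, adjusted p = 0.0131), the transporter gene Slc10a6 (2.08 ± 0.37, adjusted p = 0.0426) and the glucocorticoid-responsive gene Klf9 (0.94 ± 0.16, adjusted p = 0.0381). Osteoblast genes stood lower, with all 20 members below 0 and a median of -0.56 (adjusted p = 2.79e-13, and adjusted p = 0.434 with estimated correlation). Smpd3, needed for normal bone formation, fell (-0.74 ± 0.14, adjusted p = 0.0486), and adjusted over the list alone 17 fell. Notum (-0.82 ± 0.11, adjusted p = 0.0131), Galnt3, a glycosyltransferase gene that acts on the hormone FGF23 (-0.87 ± 0.16, adjusted p = 0.0486), and Podnl1 (-0.73 ± 0.12, adjusted p = 0.0362) fell too. Osteoclast genes stood at -0.72 (adjusted p = 1.37e-07, and adjusted p = 0.51 with estimated correlation) and circadian clock genes at 0.41 (adjusted p = 9.25e-06, and adjusted p = 0.436 with estimated correlation). The count of 82 became 1 without naive library 2, 3 without naive 3, 35 and 36 without unstimulated 3 or the pair, and 245 without naive 1; a lone unstimulated library is again assumed to vary like the other groups. It was 1 and 26 with the muscle or the marrow scores as covariates, 257 with the pair kept apart and 490 with DESeq2.

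In bone at 12 days, 1899 genes were higher and 2211 lower in unstimulated than in naive libraries. All 25 cell cycle genes fell (median -1.69; adjusted p = 1.24e-19, and adjusted p = 0.557 with estimated correlation), with Prc1 at -1.78 ± 0.18, adjusted p = 0.000573. All 17 erythroid genes fell (median -2.24; adjusted p = 2.06e-10, and adjusted p = 0.557 with estimated correlation). The erythroid share of counts was 0.654% ± 0.238 against 2.97% ± 1.88 (1.89% without naive replicate 3). Trim58 (-2.9 ± 0.44, adjusted p = 0.00203) and Trim10 (-2.85 ± 0.49, adjusted p = 0.00386), genes of red cell maturation, fell most. Other genes that fell were Slfn14 (-2.61 ± 0.47, adjusted p = 0.00428), the globin gene Hbq1b (-2.64 ± 0.50, adjusted p = 0.00466) and the immunoglobulin segment Ighv7-1 (-2.72 ± 0.70, adjusted p = 0.0207). Neutrophil genes fell in 8 of 16 cases (median -1.31; adjusted p = 9.4e-07, and adjusted p = 0.557 with estimated correlation) and lymphocyte genes in 11 of 19 (median -1.27; adjusted p = 2.02e-05, and adjusted p = 0.557 with estimated correlation). Osteoclast genes fell in 9 of 18 cases, Car2 among them (-2.05 ± 0.45, adjusted p = 0.0101; adjusted p = 2.21e-06, and adjusted p = 0.557 with estimated correlation). Higher in unstimulated bone were Coch, which encodes cochlin (5.56 ± 1.44, adjusted p = 0.0221), the complement gene C7 (3.84 ± 0.51, adjusted p = 0.00168), Cyp2e1 (3.06 ± 0.63, adjusted p = 0.00889) and Inmt (3.0 ± 0.31, adjusted p = 0.000573). Coch averaged 63.8 CPM against 1.23 CPM, but 28.1 CPM without unstimulated library 1 and, in naive bone, 0.261 CPM without naive 1. The naive means of C7 and Cyp2e1 fell from 2.52 to 1.53 CPM without naive 1 and from 20.1 to 12.1 CPM without naive 3. Prg4, which encodes the joint lubricant lubricin, rose to 4876 ± 1640 CPM against 673 ± 148 CPM (2.86 ± 0.56, adjusted p = 0.00638). Adipocyte genes rose in 11 of 22 cases, Retn among them (2.03 ± 0.28, adjusted p = 0.00168; median 0.78; adjusted p = 1.39e-06, and adjusted p = 0.557 with estimated correlation). Tendon fibroblast genes rose in 12 of 19 cases, decorin, Dcn, among them (1.35 ± 0.18, adjusted p = 0.00141; adjusted p = 0.000475, and adjusted p = 0.557 with estimated correlation). The count of 4110 became 1951 without naive library 2, 2638 without naive 3, 2376 without unstimulated 1 and 2528 without unstimulated 3. With the erythroid and neutrophil scores as covariates edgeR called 0 genes, with 1311 at an unadjusted p under the threshold.

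Stimulated bone was also set against naive bone. At 5 days 40 genes were higher and 3 lower. The largest rises were in Slc10a6 (2.2 ± 0.35, adjusted p = 0.0311), the neurotrophin receptor gene Ntrk3 (1.79 ± 0.29, adjusted p = 0.0311) and Tmeff2 (1.75 ± 0.30, adjusted p = 0.0311). Ildr2 (1.5 ± 0.24, adjusted p = 0.0311) and the vascular growth factor gene Vegfd (1.46 ± 0.24, adjusted p = 0.0311) followed. Thbs1, which encodes the matrix protein thrombospondin (-0.98 ± 0.16, adjusted p = 0.0311), Tmem200a (-1.25 ± 0.20, adjusted p = 0.0311) and Lims1 (-0.42 ± 0.07, adjusted p = 0.0395) fell. At 12 days 393 genes were higher and 463 lower. The acute-phase genes Serpina3n (2.65 ± 0.43, adjusted p = 0.0125) and Serpina3m (3.06 ± 0.52, adjusted p = 0.0124), which are close paralogues, rose. So did C7 (2.81 ± 0.50, adjusted p = 0.016), the claudin gene Cldn2 (2.66 ± 0.65, adjusted p = 0.0411) and Ces2c (2.95 ± 0.68, adjusted p = 0.0336). The stefin genes Stfa2 (-2.1 ± 0.51, adjusted p = 0.0418) and Stfa3 (-2.42 ± 0.57, adjusted p = 0.039), also near copies, fell. So did Cstdc5 (-2.09 ± 0.51, adjusted p = 0.0459), A2m (-2.3 ± 0.55, adjusted p = 0.044) and Trim58 (-1.74 ± 0.41, adjusted p = 0.0377). Without naive replicate 2 the naive means fell from 13.1 to 7.33 CPM for Stfa2, from 14.1 to 7.50 CPM for Stfa3 and from 43.5 to 26.1 CPM for Cstdc5. Without naive replicate 3 that of A2m fell from 84.9 to 43.4 CPM, and without stimulated library 2 the stimulated mean of Cldn2 fell from 2.59 to 1.56 CPM. Cell cycle genes fell in 8 of 25 cases (median -0.86; adjusted p = 1.67e-12, and adjusted p = 0.791 with estimated correlation) and osteoblast genes in 8 of 20 (median -0.54; adjusted p = 9.61e-10, and adjusted p = 0.791 with estimated correlation). Cartilage genes fell in 4 of 26 cases, Col11a1 among them (-0.91 ± 0.14, adjusted p = 0.00812; adjusted p = 0.00511, and adjusted p = 0.837 with estimated correlation). The cartilage median, -0.40, was -0.18 without naive replicate 3 (adjusted p = 0.0547) and -0.21 without stimulated 3 (adjusted p = 0.227).

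The 5-day count of 43 became 1 without naive library 2, 2 without naive 3 or stimulated 1, 3 without stimulated 3, 10 without stimulated 2 and 82 without naive 1. It was 664 with DESeq2, 24 with the muscle score, 2 with the marrow scores and 159 with the pair kept apart. The 12-day count of 856 became 108 without naive library 2, 173 without stimulated 2, 192 without naive 3, 546 without stimulated 1 and 1307 without naive 1. It was 175 with the muscle score, 20 with the marrow scores, 1294 with the pair kept apart and 1908 with DESeq2.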

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

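The comparison of tissues was planned; the splits of the libraries and the tests of a tissue share, of marrow share, of muscle RNA in bone and of muscle share were chosen only after the results were seen, and those of depth and of genes expressed in muscle fibres before. The tests of a tissue share and of marrow share replaced earlier ones on 1 pair of lists each, which had not argued against a share, and their bound was set with the tendon outcome known.

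At 12 days the effect of stimulation differed between tendon and bone for 44 genes (edgeR interaction test). Of 40 splits only the real one gave as many, and the highest other gave 17. The replicate block left 10 genes, so chance is not excluded. Genes named for tendon that passed with a higher effect there were Eno2 (1.74 log2), Ppm1e (2.05), Nab2 (1.90) and Hbegf (2.28). Those with a lower effect in tendon were Irx5 (-4.42, at 2 to 3 counts per stimulated tendon library), Tiam1 (-1.20) and Pdcd4 (-0.57).

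The genes higher in stimulated tendon at 12 days include several known from muscle, such as Nmrk2 and Ppargc1a, and each tendon library held muscle RNA. A larger share of muscle in the stimulated libraries is argued against: the muscle fibre score differed by -0.23 (SE 0.18), while the smallest rise of the 49 genes was 0.41. With the muscle score as a covariate only 6 of the 49 were still called, as their median change went from 1.09 to 0.97 (median SE 0.16 in both) with all 49 above 0, and their median adjusted p from 0.0234 to 0.106. That these genes are expressed in muscle fibres remains open. Across bone libraries 36 of the 49 (73.5%) went with the muscle score, against a median of 44.9% in 10000 random lists of equal size. That test leans on naive replicate 3 (score 1.56, others 6.83 or more). A hypothesis is that part of the rise may come from a changed state of muscle fibres in or near the tendon samples. A response of tendon cells stays open too.

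Tendon, collagen and matrix genes were lower in 12-day unstimulated than in naive tendon. Library depth is argued against, since after thinning all libraries to 24.5 M counts 50 of 52 such called genes were still called lower (3000 calls in all against 3209). Markers of other cell types cannot decide on a smaller share of tendon tissue, because types lying within that tissue would fall with it. Of 21 pairs of these lists 11 moved apart by over 2 standard errors, most clearly muscle fibre against macrophage genes (1.41, SE 0.18). The widest pair, Schwann cell against erythroid genes, was uncertain (SE of the Schwann score 1.13). A smaller share of tendon tissue, a change in dissection that altered several tissues at once, age, and a change in tendon cells between day 0 and day 12 stay open. No test separates them.

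Cell cycle and erythroid genes were lower in 12-day unstimulated than in naive bone. Muscle RNA carried into bone is argued against, because 25 of 25 cell cycle genes were still called lower with the muscle score as a covariate. A smaller share of marrow as a whole cannot be told apart from a change within marrow: of 6 pairs of marrow lists 1 moved apart, megakaryocyte against erythroid genes (1.21, SE 0.58), and macrophage genes, many of them also of marrow, did not go down (0.25, SE 0.16). Age and the days of housing differ with the group and stay open.

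The other splits of the libraries were counted for each comparison of groups of 3 against 3, which allow only 10 splits, too few for a share under 0.05. The real count and the highest of the others were 59 and 1 for 12-day tendon with and without stimulation, 7 and 1 for 12-day bone, 3209 and 1 for 12-day unstimulated against naive tendon, and 4110 and 0 in bone. They were 392 and 0, and 4169 and 0, for stimulated against naive tendon, 43 and 0, and 856 and 0, for stimulated against naive bone, and 13569 and 0 for naive tendon against naive bone. In each of these 1 of the 10 splits gave as many. In 5-day tendon 2 of 10 splits gave as many: stimulated against unstimulated called 10 genes and the highest other split 163, and unstimulated against naive called 6 and the highest other 360, which points to a structure of these samples other than their groups. For the change of the tendon effect between days all 40 splits gave at least the real count of 0, and the highest gave 383.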

How the results depend on the processing

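Of the alternatives below, the tendon score, the scores in comparisons with naive samples, the near-identical pair kept apart and bone without naive replicate 3 were chosen only after the results were seen; the others were planned. For genes picked by the naming rules, 1031 of 1539 recomputed values kept direction and side of the threshold, 460 kept direction but no longer passed, 21 passed only under the alternative, 27 values without a test moved and 0 changed direction. Of 1959 values of lists, 1429 kept direction and side, 516 kept direction but no longer passed, and 14 medians changed sign. The cause of these changes was not tested beyond what a setting itself does, such as fewer libraries or genes.

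Stimulated against unstimulated, the counts were, for 5-day tendon (10 as reported), 12-day tendon (59), 5-day bone (0) and 12-day bone (7), 127, 368, 44 and 386 by DESeq2. With only the libraries compared they were 0, 0, 0 and 0 (1162, 1471, 1725 and 2042 at an unadjusted p). By limma-voom with quality weights they were 2507, 231 and 4, with no change over 1.5 times in 12-day bone. Without a count filter 5-day tendon gave 17, 5-day bone 1 and 12-day bone 32. The muscle score left 10 genes in 12-day tendon and 1 in 12-day bone, the marrow scores 0 in 12-day bone (916), DESeq2's size factors 1 there, and the tendon score 26 in 5-day tendon. With the pair kept apart 5-day bone gave 3 and 12-day bone 11.

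Against naive, DESeq2 called 109 and 490 for 5-day unstimulated tendon and bone, 1055 and 664 for the 5-day stimulated ones, and 1908 for 12-day stimulated bone. The tendon score left 2 and 10 genes in unstimulated tendon at 5 and 12 days and 12 and 45 in stimulated tendon. The muscle score left 1 and 1524 in unstimulated tendon, 208 in 5-day stimulated tendon, 1 in 5-day unstimulated bone and 24 and 175 in stimulated bone. The marrow scores left 26 and 0 in unstimulated bone (1311 at an unadjusted p in the latter) and 2 and 20 in stimulated bone. With the pair kept apart, 5-day unstimulated bone gave 257 and stimulated bone 159 and 1294. For differences of the effect, DESeq2 called 5 between days in tendon, 60 in bone, and 47 and 190 between tissues at 5 and 12 days; bone between days gave 1 without a filter and 1 with the pair kept apart, and the tissues at 5 days 9.

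As a replicate block, the number moved the counts to 0 in 12-day tendon and 0 in 12-day bone with and without stimulation (1630 and 1730 at an unadjusted p), to 743 for 5-day stimulated against naive tendon, 8 for 5-day stimulated against naive bone and 10 for the tissues at 12 days; no other count moved over 1.5 times. No comparison had all pairs of equal number correlated above 0.1, but 3 pairs cannot exclude pairing. The block was not run where 5-day unstimulated bone enters, because its pair had been summed, and the covariate for sex was not run because all samples were of the same sex.

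Leaving out a library of 5-day unstimulated bone leaves 1, assumed to vary like the other groups. Leaving out each library in turn, the counts ranged from 0 to 20 and from 2 to 672 in stimulated against unstimulated tendon at 5 and 12 days, and from 0 to 14 and from 0 to 7 in bone. Unstimulated against naive, they ranged from 1 to 297 and from 85 to 2609 in tendon and from 1 to 245 and from 1951 to 4062 in bone. Stimulated against naive, they ranged from 7 to 336 and from 1649 to 4723 in tendon and from 1 to 82 and from 108 to 1307 in bone. Between days they ranged from 0 to 11 in tendon (11 without 12-day stimulated library 2, 1 without 5-day stimulated 3) and from 0 to 3 in bone (3 without 5-day unstimulated 3, 1 without 12-day stimulated 2). Between tissues they ranged from 0 to 10 at 5 days and from 9 to 356 at 12 days. At 5 days the 10 came without tendon stimulated library 3, 3 without tendon unstimulated 1, 2 without bone unstimulated 3 and 1 without bone stimulated 1. Naive tendon against naive bone stayed between 12719 and 13122.

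With the correlation between genes estimated, 0 lists passed in each of the 12 comparisons. By fry 0 lists passed in the 4 comparisons of stimulated with unstimulated, and against naive 1 and 17 in unstimulated tendon at 5 and 12 days (16 and 22 by camera), 2 and 15 in unstimulated bone (24 and 20), 3 and 23 in stimulated tendon (22 and 27) and 0 and 1 in stimulated bone (17 and 15). Of these camera calls, leaving out some library ended 6 and 4, 10 and 2, 7 and 6, and 6 and 5. Without each library in turn 9 to 16 lists passed in 5-day tendon (14 as reported) and 5 to 8 in 12-day tendon (8 as reported). List medians changed sign in stimulated against unstimulated tendon for collagens at 5 days (-0.50 to 0.0133), adipocyte genes at 5 days (-0.0023 to 0.92), osteocyte genes at 12 days (-0.30 to 0.10) and ribosomal protein genes at 12 days (-0.0035 to 0.10), and in bone for immediate early genes at 12 days (-0.37 to 0.0285). Against naive they changed sign for cell cycle genes in 5-day unstimulated tendon (-0.70 to 0.12), oxidative phosphorylation genes in 5-day stimulated tendon (-0.0292 to 0.28), and erythroid (-0.61 to 0.0671), muscle fibre (-0.56 to 1.16) and Schwann cell genes (-0.21 to 1.99) in 5-day stimulated bone.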

Other observations

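The lists below were fixed in advance, and the members named were those with the smallest adjusted p. Glucocorticoid-responsive genes stood higher than other genes in every comparison of unstimulated or stimulated samples with naive ones. In 5-day stimulated tendon Fkbp5 (1.84 ± 0.14, adjusted p = 5.2e-05), Mt1, Mt2 and Zbtb16 (0.73 ± 0.15, adjusted p = 0.026) rose (list median 0.78; adjusted p = 1.62e-06, and adjusted p = 0.106 with estimated correlation; fry adjusted p = 0.000875). In 12-day tendon the list median was 0.30 in unstimulated (adjusted p = 0.0215, and adjusted p = 0.351 with estimated correlation) and 0.37 in stimulated libraries (adjusted p = 0.0156, and adjusted p = 0.333 with estimated correlation). There the rises were 0.61 ± 0.15, adjusted p = 0.0172, for Zbtb16 in unstimulated and 1.42 ± 0.13, adjusted p = 0.000151, for Fkbp5 in stimulated libraries. In bone the median was 0.94 in unstimulated libraries at 5 days (adjusted p = 1.82e-06, and adjusted p = 0.434 with estimated correlation). At 12 days it was 0.79 (adjusted p = 0.000475, and adjusted p = 0.557 with estimated correlation), with Klf9 at 1.0 ± 0.15, adjusted p = 0.00179, and Mt2 at 2.58 ± 0.57, adjusted p = 0.0118. In stimulated bone it was 0.56 (adjusted p = 7.83e-05, and adjusted p = 0.808 with estimated correlation) and 0.58 (adjusted p = 0.00986, and adjusted p = 0.791 with estimated correlation). Of these 8 calls 3 ended when some library was left out. In 12-day unstimulated tendon the median was 0.0751 without unstimulated library 2 (adjusted p = 0.0695) and 0.22 without naive 1 (adjusted p = 0.107). In 12-day stimulated tendon it was 0.32 without naive 1 (adjusted p = 0.0644) and 0.30 without stimulated 2 (adjusted p = 0.0669), and in 12-day stimulated bone 0.50 without stimulated 2 (adjusted p = 0.0809). Without unstimulated library 1 the mean of Mt2 in 12-day unstimulated bone fell from 136 to 84.3 CPM. These comparisons share their naive libraries, so they are not independent of each other.

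Interferon-stimulated genes stood lower than other genes in all 8 comparisons with naive samples, with medians of -0.82 to -0.33 (adjusted p = 0.00986 or less, and 0.360 to 0.837 with estimated correlation). The 12-day unstimulated tendon call (-0.47) ended without naive library 1 (-0.30, adjusted p = 0.139), and no other did without any library. The median was -0.61 in 5-day unstimulated tendon (adjusted p = 1.55e-09, and adjusted p = 0.405 with estimated correlation), where 13 fell when adjusted over the list alone and 0 over all genes. In 12-day unstimulated bone it was -0.70 (adjusted p = 1.39e-06, and adjusted p = 0.557 with estimated correlation), and 11 of 22 fell, with Isg15 at -1.85 ± 0.34, adjusted p = 0.00434. Circadian clock genes stood higher in 12-day unstimulated than in naive bone (0.51; adjusted p = 9.73e-05, and adjusted p = 0.557 with estimated correlation), Clock among the 8 that rose (0.51 ± 0.09, adjusted p = 0.00271). The hour of sampling is not given in the sources used here. Axon guidance genes stood lower in 12-day unstimulated than in naive tendon (-0.72; adjusted p = 8.16e-05, and adjusted p = 0.351 with estimated correlation), with the axon receptor gene Robo1 at -1.42 ± 0.25, adjusted p = 0.00951. So did TGF-beta and BMP genes (-0.56; adjusted p = 4.36e-06, and adjusted p = 0.351 with estimated correlation). Schwann cell genes stood higher in 12-day unstimulated than in naive bone (1.07; adjusted p = 0.0012, and adjusted p = 0.621 with estimated correlation), with Scn7a at 1.61 ± 0.32, adjusted p = 0.0061.

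Other list values were, in 5-day tendon with and without stimulation, 0.27 for adipocyte genes (adjusted p = 0.0109, and adjusted p = 0.773 with estimated correlation) and -0.15 for endoplasmic reticulum stress genes (adjusted p = 0.0421, and adjusted p = 0.773 with estimated correlation). For ribosomal protein genes the median was 0.09 (adjusted p = 0.000403, and adjusted p = 0.773 with estimated correlation). In 12-day tendon osteocyte genes stood at -0.18 (adjusted p = 0.0483, and adjusted p = 0.684 with estimated correlation), with Irx5 the single member that fell. This call ended without any 1 of the 6 libraries and passed under 0 of 9 alternatives. YAP/TEAD and SRF targets stood at -0.33 (adjusted p = 0.0379, and adjusted p = 0.986 with estimated correlation), although Ankrd1 stood at 1.23 ± 0.33, adjusted p = 0.136. Ribosomal protein genes stood at 0.07 (adjusted p = 0.0461, and adjusted p = 0.986 with estimated correlation). In 12-day bone keratinocyte genes stood at -0.34 (adjusted p = 0.0257, and adjusted p = 0.521 with estimated correlation) and Schwann cell genes at -0.91 (adjusted p = 0.0081, and adjusted p = 0.725 with estimated correlation). Immediate early genes stood at -0.30 (adjusted p = 0.0418, and adjusted p = 0.725 with estimated correlation) and YAP/TEAD and SRF targets at -0.14 (adjusted p = 0.0351, and adjusted p = 0.602 with estimated correlation). Cartilage genes stood at -0.13 (adjusted p = 0.0292, and adjusted p = 0.772 with estimated correlation) and circadian clock genes at -0.17 (adjusted p = 0.0163, and adjusted p = 0.521 with estimated correlation). Several of these calls end when 1 library is left out. In 5-day tendon the adipocyte call ended without 4 of the 6 libraries, with a median of 0.0020 without unstimulated library 1 (adjusted p = 0.621), and the ribosomal median was 0.0177 without unstimulated 3 (adjusted p = 0.612). The endoplasmic reticulum call ended without 3 of the 6. In 12-day tendon the YAP/TEAD call ended without 4 of the 6 libraries and the ribosomal call without 3. In 12-day bone Schwann cell genes stood at -0.48 without unstimulated library 3 (adjusted p = 0.131), immediate early genes, lost without 3 libraries, at 0.0285 without unstimulated 1 (adjusted p = 0.784), cartilage genes, also lost without 3, at -0.0395 without stimulated 3 (adjusted p = 0.602) and circadian clock genes at -0.0916 without stimulated 1 (adjusted p = 0.227). The keratinocyte call ended without unstimulated 2 (adjusted p = 0.0617) and the YAP/TEAD call without 4 of the 6 libraries.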
